A study of Hordeum vulgare with 40 samples.

How the data were processed

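Gene expression was measured in the lower stem segment (about 1.5 cm) of seedlings of the barley cultivar Nure on 2-colour Agilent oligonucleotide arrays. Per the labels, seedlings were grown at 20 °C with 16 h of light per day for 3 days, then given water, lanthanum (1 mM), EGTA (10 mM) or mastoparan (10 µM) for 24 h, and were then moved to 4 °C or kept at 20 °C for another 24 h. Lanthanum blocks calcium channels of the plasma membrane, EGTA binds extracellular calcium, and mastoparan is a wasp venom peptide that activates heterotrimeric G proteins; they are called inhibitors here. These 4 pretreatments at 2 temperatures make 8 conditions. Each condition had 2 biological replicates, which the labels describe as separate harvests of pooled plants; each gave 1 RNA extract, so that n = 2 extracts per condition and 16 extracts in all. The labels do not settle how many plants or technical portions went into a pool.

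Per the labels' protocols, RNA was isolated with TRIzol, treated with DNase I, amplified to cRNA and labelled with Cy3 or Cy5 by Agilent's procedure. Each array held 2 extracts of 1 replicate number, 1 per dye. The 40 arrays lie on 10 slides of 4 arrays, and each slide holds 1 comparison: both biological replicates, each hybridised in both dye orientations. The slides set each inhibitor against water at both temperatures, and cold against normal temperature after each pretreatment. The slides were scanned in 3 batches. Both conditions of a comparison sit on each array, so every ratio is within 1 slide and 1 scan.

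The scanner files came from Agilent's Feature Extraction software, per the file headers, and hold 45220 spots per array. The columns used here are the mean signal and the local background of each channel, deposited as intensity on a linear scale with no normalization, and marks of 0 or 1 for spots well above background, non-uniform or saturated, per the file headers. The software's processed signals, also deposited as intensity, are background-subtracted and dye-normalized with a linear and lowess method, per the file headers. The deposited log ratio column is log10 of red over green processed signal, per the file headers, and was not used beyond a check of direction. The authors also deposited a value table for the series on a log2 scale. Set against the scanner values, each of its columns followed log2 of red over green (r from 0.855 to 0.999 across spots, slope from 0.853 to 1.38) with a median between -0.03 and 0.03; its background correction and normalization are not given in the sources used here. R 2.12.0 and limma are named without a role, per the submitters' processing notes.

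From the scanner files, background was corrected with normexp (offset 50) on all spots and log ratios were normalized within each array by loess with control spots at weight 0. Ratios were turned so that treatment stood over reference according to the dyes in the labels. Control spots and the 2396 spots marked as non-uniform or population outliers over all arrays were left out, and spots of 1 probe were averaged, giving 43603 probes. Dye-swapped arrays of the same pair of extracts were averaged, which gave 20 ratios. Within each replicate, least squares over its 10 ratios gave the log2 level of each of the 8 extracts relative to their mean; 1 probe was left without a level in an extract. A comparison is therefore drawn from its own slide and, through shared extracts, from the others; the values from its own slide alone are called direct ratios. The labels were taken to mean that an extract of the same name was the same RNA on each of its arrays. For each inhibitor and replicate, the 2 routes around the loop of 4 conditions correlated across probes with r between 0.761 and 0.874.

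A probe was tested where it was well above background on at least 75% of the arrays and channels of at least 1 condition, which kept 30377 probes. limma (lmFit and eBayes, moderated test, two-sided) was fitted to the 16 levels with 8 condition means and the replicate number as a block, leaving 7 residual degrees of freedom. No array crosses the replicate numbers of the labels, which gives the pairing, so the block is inherent in the hybridisation plan. In separate-channel levels, deviations of same-numbered extracts from their condition means correlated in 26 of 28 pairs of conditions above 0.1 (median 0.331, range 0.036 to 0.536). The 10 comparisons of the slides and 3 differences of cold responses (inhibitor minus water) were tested, with Benjamini-Hochberg adjustment over the tested probes of each; a probe passed at an adjusted p under 0.05. The 2 extracts per condition limit the precision: the median SE of a log2 change was 0.06 for a comparison and 0.09 for a difference. The SE pools a probe's spread over all 8 conditions, so it does not give the spread within 1 comparison.

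Gene names come from the probe descriptions in the files. None of the accessions matched the RefSeq gene table given for barley (0 of 43603 probes), so these older names were kept: 5007 probes have an informative name (4383 of them tested), often from the best sequence match in wheat, rice or another plant. Probes of multigene families may hybridise with several members, and no genome positions are given. The genes named were chosen by rule: for cold after water the 12 probes with the largest rise and the 12 with the largest fall past the threshold, with the same direction in both replicates and an informative name, 1 probe per description; 6 and 6 by the same rule for every other comparison and difference; and up to 4 members with the largest change past the threshold from each gene list. A description can therefore stand for different probes in different comparisons (marked for the 12 or 6 largest changes as another probe). Every named gene thus moved the same way in 2 of 2 replicates. None of the 352 named probes and list members was saturated on any array.

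The 26 gene lists were defined by expressions over gene names: C-repeat binding factors (CBF and DREB), dehydrins and late embryogenesis proteins, cold-regulated proteins, heat shock proteins and chaperones, calcium sensors and calcium-regulated kinases, calcium and cation transport, metal homeostasis, G protein and phospholipid signalling, photosynthesis, sugar metabolism (fructan, sucrose and raffinose), starch and storage reserves, defence proteins, oxidative stress enzymes, cell wall, ethylene, jasmonate and lipoxygenase, abscisic acid, auxin, gibberellin, phenylpropanoids and flavonoids, WRKY/NAC/MYB factors, lipid transfer proteins and desaturases, cytosolic ribosomal proteins, histones and DNA replication, vernalization and MADS box genes, and proline and polyamine synthesis. They hold 1143 probes on the array, 985 of them tested. Words that matched by accident were removed from 10 of the lists after the names had been read but with no expression value seen. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 338 list tests, and again with an estimated correlation; no list call held with the estimated correlation (adjusted p from 0.419 to 0.95).

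The share of the cold response kept under an inhibitor was computed from direct ratios: probes with an absolute log2 ratio of at least 1 on the water slide in 1 replicate were measured in the other. The agreement of inhibitor effects is the correlation and covariance across probes of 1 inhibitor's effect in replicate 1 with another's in replicate 2, set beside 20 simulated draws with shared water extracts and no effect. Probes are not independent replicates in these values.

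The steps were tested on simulated data with 200 changed probes. For cold against normal temperature after water the fit over 28765 simulated probes recovered 73.1% of the changes of log2 0.5, 95.5% of those of log2 1 and 100% of those of log2 2, with 2.19% of the calls false, and over 20 draws with no effect a contrast gave at most 1 call. The simulated share kept of 60% was returned as 60.0% (EGTA), and a covariance set at 0.02 as 0.0192.

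The groups, the model, the lists, the naming rule and these alternatives were fixed before the data were examined: no background subtraction; median centring in place of loess; the processed signals, median-centred; the authors' value table; no filter and a stricter one (well above background on every array, 20429 probes); direct ratios only; all 40 arrays as separate ratios with a dye term; separate-channel levels without the replicate block; a prior with intensity trend and robust fitting, with brightness taken from the separate channels; a 2-fold minimum; each extract left out; an estimated correlation for the lists; and a log2 minimum of 2 for the share kept. Further alternatives were chosen after seeing the data: lists without the removals, camera on direct ratios, and each comparison without its own slide. The depth of an array is its signal over background: 47.8% to 75.2% of the spots were well above background in green and 60.1% to 75.1% in red, with median signals of 61.0 to 212 and 71.0 to 134 intensity units. R 4.3.3 with limma 3.58.1, statmod 1.5.0, data.table (version 1.17.8) and jsonlite 2.0.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, were used.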

Results

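The arrays compared the lower stem of barley seedlings in 10 pairs of conditions. Cold was set against normal temperature after water, lanthanum, EGTA or mastoparan, and each inhibitor against water at both temperatures. Every condition was read on 8 to 16 arrays. Over the 4 arrays of a comparison, log ratios correlated with r between 0.846 and 0.96 for cold after water, but between 0.105 and 0.602 for lanthanum against water at normal temperature. Values are log2 changes ± SE (n = 2 extracts per condition, spread pooled over conditions). Adjusted p-values are limma's for probes and camera's for lists. List counts are of probes, and several can belong to 1 gene. Per its title, the series asked how depleting calcium affects cold-induced expression.

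The largest rise in the cold after water was that of a dehydrin, which stabilises membranes and proteins in dehydrated cells (4.91 ± 0.14, 30.1-fold). The early light-inducible proteins HV58 (4.65 ± 0.13), HV60 (4.62 ± 0.21) and HV90 (4.44 ± 0.19) bind chlorophyll under stress. They rose with 2 further ELIP clones (4.13 ± 0.11 and 3.66 ± 0.21). The abscisic acid-inducible embryogenesis protein PHV A1 rose 12.4-fold (3.63 ± 0.44), a plasma membrane proton ATPase by 3.52 ± 0.25 and the cold acclimation protein WCOR615 by 3.45 ± 0.09. Ribonuclease (3.03 ± 0.17), the chlorophyll a/b-binding protein WCAB (2.88 ± 0.19) and a zinc finger protein (2.85 ± 0.08) completed the 12 largest rises.

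The largest falls after cold included several defence genes. Cyanate hydratase was 8.70-fold lower (-3.12 ± 0.22), and beta-1,3-glucanase 2a, which digests fungal cell walls, 6.61-fold lower (-2.72 ± 0.21). WIR1A (-2.26 ± 0.20), the stem rust resistance gene Rpg1 (4.34-fold lower), PR-1a (4.33-fold lower, adjusted p = 0.0381) and PRB1-2 (-2.04 ± 0.73, adjusted p = 0.0381) also fell. So did the splicing factor subunit U2AF (-2.31 ± 0.07), a peroxidase (-2.18 ± 0.31), Seed imbibition protein (-2.17 ± 0.15), the receptor kinase MRKa (-2.10 ± 0.31) and Light-induced protein 1-like (-2.03 ± 0.16). A nonspecific lipid transfer protein had a mean change of -2.88 ± 0.61 with unequal replicates, -4.20 and -1.55. PR-1a and PRB1-2 missed the threshold under median centring (adjusted p = 0.0728 and 0.07), with processed signals (0.0663 and 0.0783), with no filter (0.0551 for each) and with the trend prior (0.0732 for each). PRB1-2 also missed it with the authors' value table (0.0548).

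**Figure D1:**
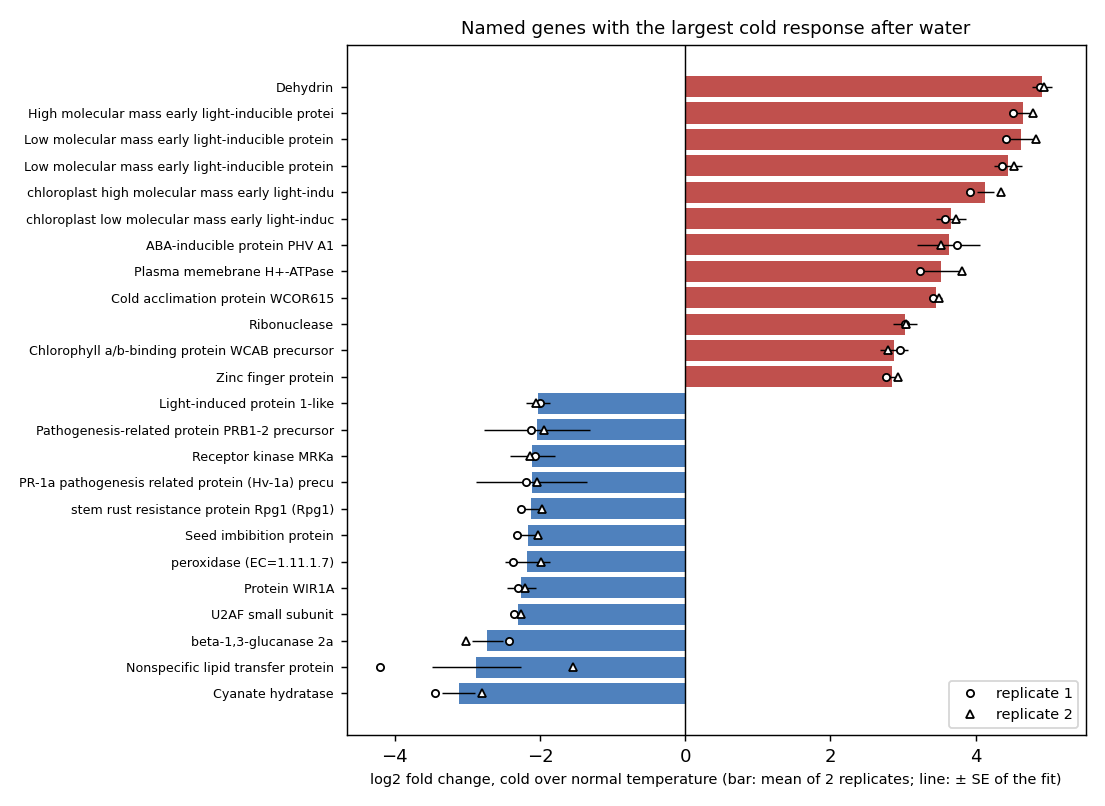
Log2 fold change of cold over normal temperature after water (horizontal axis) for the 24 named genes with the largest changes, with bars for means of 2 replicates, lines for the SE, and circles and triangles for replicates 1 and 2.

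Among the gene lists, 5 moved in the cold after water. Of 25 tested abscisic acid probes 14 rose and 3 fell (15 and 3 adjusted over the list alone, adjusted p = 0.00577). ABA-responsive protein rose 4.34-fold, and a protein phosphatase 2C, of a class that damps the hormone's signal, by 0.90 ± 0.05. Of 19 cold-regulated protein probes 11 rose and 6 fell (11 and 6 adjusted over the list alone, adjusted p = 0.0485), with lt101.1 at 2.72 ± 0.15, ice recrystallization inhibition protein 1 at 2.44 ± 0.29 and WCOR413 at 1.88 ± 0.12. Of 176 histone and DNA replication probes 80 rose and 35 fell (81 and 37 adjusted over the list alone, adjusted p = 0.0216), with H2B.5 at 1.49 ± 0.10. Defence proteins moved down, 1 rising and 25 falling of 67 (0 and 20 adjusted over the list alone, adjusted p = 0.00559). Cell wall genes moved down too, 5 and 18 of 49 (5 and 17 adjusted over the list alone, adjusted p = 0.0485). Among them a xyloglucan endotransglycosylase (-1.73 ± 0.08) and the expansins EXPB9 (-1.54 ± 0.12) and EXPA1 (-1.51 ± 0.16), which loosen growing walls, fell. No call held with an estimated correlation (adjusted p = 0.95 for histones and 0.902 for the others). The cell wall call ended with no background subtraction (0.0685), median centring (0.411) and processed signals (0.0559), the cold-regulated call with processed signals (0.0559), and the defence call in the list without removals (0.0833).

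The other lists did not pass in this comparison (adjusted p from 0.0675 to 0.942). Among 14 dehydrin probes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Dehydrin 13 at 2.45 ± 0.07, HVA22 at 1.19 ± 0.13 and DHN1 at 0.73 ± 0.11. Of 8 probes of CBF and DREB factors, which switch on cold genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone). CBF9 rose by 2.75 ± 0.11, the pseudogene CBF8B fell by 1.69 and CBF4A by 0.66, while DREB1 stood at -0.14 and turned to 0.09 under median centring. Calcium sensors and kinases split, 10 higher and 19 lower of 48 (11 and 21 adjusted over the list alone, adjusted p = 0.238). A cyclic nucleotide-gated, calmodulin-binding channel stood at -0.78, CDPK2 at 0.78 ± 0.07 and CIPK6 at 0.62 ± 0.10. Of 6 calcium and cation transport probes 3 rose and 2 fell (3 and 2 adjusted over the list alone), with Glutamate receptor 3.4 at 1.06 ± 0.09. Of 62 heat shock protein and chaperone probes 19 rose and 18 fell (19 and 18 adjusted over the list alone). Sugar metabolism had 10 up and 4 down of 23 (11 and 4 adjusted over the list alone). Galactinol synthase, which starts raffinose synthesis, rose by 1.96 ± 0.15 and soluble acid invertase by 1.46 ± 0.14. Phenylpropanoid and flavonoid synthesis had 13 and 13 of 37 (13 and 14 adjusted over the list alone), with cinnamyl alcohol dehydrogenase at 2.02 ± 0.10. Photosynthesis had 10 and 18 of 46 (10 and 19 adjusted over the list alone), with the P700 apoprotein of photosystem I at 1.51 ± 0.12.

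For the remaining lists, counts of probes higher and lower in the cold after water follow. Oxidative stress enzymes had 37 and 43 of 115 (39 and 46 adjusted over the list alone) and ribosomal proteins 21 and 18 of 72 (21 and 18 adjusted over the list alone). WRKY, NAC and MYB factors had 13 and 12 of 44 (13 and 12 adjusted over the list alone). G protein and phospholipid signalling had 11 and 6 of 32 (11 and 7 adjusted over the list alone), ethylene 7 and 3 of 15 (8 and 3 adjusted over the list alone) and auxin 6 and 8 of 22 (6 and 8 adjusted over the list alone). Metal homeostasis had 3 and 7 of 24 (3 and 7 adjusted over the list alone), and lipid transfer proteins and desaturases 6 and 5 of 17 (6 and 5 adjusted over the list alone). Starch and storage reserves had 4 and 2 of 27 (4 and 1 adjusted over the list alone) and jasmonate 3 and 2 of 23 (3 and 2 adjusted over the list alone). Gibberellin had 2 and 4 of 13 (2 and 4 adjusted over the list alone), and proline and polyamine synthesis 1 and 1 of 4 (1 and 1 adjusted over the list alone). Of 5 vernalization and MADS box probes limma called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with direct ratios). Median, mean and camera's direction were not all of 1 sign for the CBF, oxidative stress, jasmonate, lipid transfer and WRKY lists, none of which passed.

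In all, 15501 of 30377 probes changed in the cold after water, 7580 higher and 7921 lower (860 and 618 at least 2-fold). Direct ratios called 7932 and 8618, and replicate changes correlated across probes with r = 0.962. The majority turned with median centring (11684 higher and 4191 lower), no background subtraction (8660 and 8604) and processed signals (8992 and 7888). The count was 9436 without normal water replicate 1 and 9896 without cold water replicate 1.

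**Figure D2:**
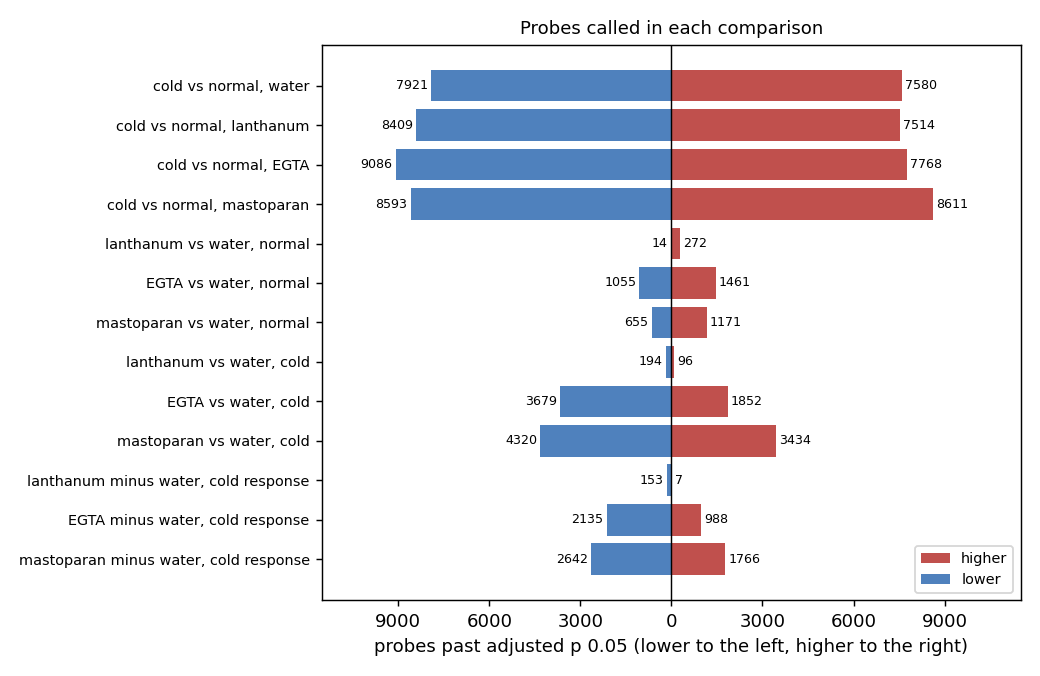
Number of probes past an adjusted p of 0.05 (horizontal axis), lower to the left and higher to the right, in the 10 comparisons and 3 differences of cold responses. Cold changed 15501 to 17204 of 30377 probes after each pretreatment, and the inhibitors 286 to 7754, and under median centring the split for cold after water moves to 11684 higher and 4191 lower.

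After lanthanum the strongest cold responses were again those of the dehydrin (4.75 ± 0.14, 26.9-fold), HV58 (4.40 ± 0.13), HV60 (3.91 ± 0.21) and HV90 (3.77 ± 0.19). An ELIP clone (3.67 ± 0.11) and PHV A1 (3.50 ± 0.44) followed. The lipid transfer protein (-3.11 ± 0.61), cyanate hydratase (-2.88 ± 0.22), a peroxidase (-2.55 ± 0.31) and Peroxidase 5 (-2.52 ± 0.12) fell. HvIRO2, a regulator of iron uptake (-2.54 ± 0.54), and the heat shock factor RHSF13-like (-2.43 ± 0.17) fell as well. Histones moved up, 81 rising and 33 falling of 176 (82 and 34 adjusted over the list alone, adjusted p = 0.00352). Dehydrins did too, 6 and 2 of 14 (6 and 2 adjusted over the list alone, adjusted p = 0.0257), with Dehydrin 13 at 2.11 ± 0.07 and DHN1 at 1.47 ± 0.11. Cell wall genes moved down, 6 and 20 of 49 (6 and 20 adjusted over the list alone, adjusted p = 0.0223), a call that ended under median centring (0.0506). No call held: adjusted p = 0.93 for histones, 0.793 for dehydrins and 0.902 for the cell wall with an estimated correlation. In all, 7514 probes were higher and 8409 lower (720 and 748 at least 2-fold). Direct ratios gave 7960 and 8826, but the majority turned under median centring (8949 and 4750) and with processed signals (8432 and 7623).

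After EGTA, HV58 (another probe than after water) rose 33.2-fold in the cold (5.05 ± 0.07), followed by HV60 (another probe, 4.80 ± 0.21), the dehydrin (4.64 ± 0.14), HV90 (4.36 ± 0.19) and both ELIP clones (4.33 ± 0.11 and 4.03 ± 0.21). The lipid transfer protein was 18.8-fold lower (-4.23 ± 0.61) and hvnas2, a nicotianamine synthase that makes a metal chelator, 14.8-fold lower (-3.89 ± 0.53). A ZIM motif protein, of a family with repressors of jasmonate signalling, was 14.7-fold lower (-3.88 ± 0.41). A Bowman-Birk proteinase inhibitor (-3.16 ± 0.24), RHSF13-like (-2.92 ± 0.17) and a thioredoxin fold protein (-2.91 ± 0.12) also fell. Histones moved up with 86 rising and 33 falling (89 and 34 adjusted over the list alone, adjusted p = 0.000337), H2A at 1.67 ± 0.07. Dehydrins moved up with 7 and 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0178), DHN1 at 2.20 ± 0.11. Cell wall genes moved down with 7 and 22 (7 and 22 adjusted over the list alone, adjusted p = 0.00893), EXPB4 at -2.09 ± 0.17. For histones, dehydrins and the cell wall, adjusted p = 0.919, 0.748 and 0.902 with an estimated correlation. The dehydrin call also ended with processed signals (0.0653). In all, 7768 probes were higher and 9086 lower (658 and 1059 at least 2-fold), and direct ratios gave 8141 and 9333. Processed signals turned the majority (10224 and 8237), and median centring gave 5359 and 8357.

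After mastoparan, HV60 rose 36.5-fold in the cold (5.19 ± 0.21), HV58 (the probe given for EGTA) by 5.11 ± 0.07, the dehydrin by 4.84 ± 0.14, the ELIP clones by 4.54 ± 0.11 and 3.94 ± 0.21 and HV90 by 4.19 ± 0.19. The ZIM motif protein (another probe than for EGTA, -3.60 ± 0.34), the Bowman-Birk inhibitor (-3.22 ± 0.24), the thioredoxin fold protein (-2.90 ± 0.12) and Light-induced protein 1-like (-2.64 ± 0.16) fell. The lipid transfer protein (-2.63 ± 0.61) and CIPK22, a kinase that partners calcium sensors (-2.60 ± 0.13), fell too. Histones moved up, 100 rising and 25 falling (101 and 26 adjusted over the list alone, adjusted p = 3.84e-05). So did ribosomal proteins, 42 and 10 of 72 (45 and 10 adjusted over the list alone, adjusted p = 0.000126), with L44 at 1.05 ± 0.06. Cell wall genes moved down, 5 and 25 (5 and 26 adjusted over the list alone, adjusted p = 0.00425). Defence proteins did too, 6 and 22 (5 and 21 adjusted over the list alone, adjusted p = 0.0253), with beta-1,3-glucanase 2a at -2.37 ± 0.21, a call that ended in the list without removals (0.0857). None held: adjusted p = 0.91 for histones and 0.902 for the others with an estimated correlation. In all, 8611 probes were higher and 8593 lower (725 and 990 at least 2-fold), and direct ratios gave 9701 and 8830, but median centring 6628 and 6844.

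Most of the cold response was shared by the 4 pretreatments. After all 4, 5089 probes rose (480 of them at least 2-fold each time) and 5488 fell (358 at least 2-fold). Of the 7580 probes that rose after water, 6252 also rose after lanthanum, 5719 after EGTA and 5609 after mastoparan, against 1875, 1938 and 2149 for independent lists. Probes chosen on 1 water replicate (log2 ratio of at least 1) were measured in the other. They kept 91.1% ± 8.93 (SD, n = 2) of their mean response after lanthanum, 86.7% ± 4.39 after EGTA and 80.7% ± 8.24 after mastoparan. Their mean log2 response was 1.49 after water against 1.34, 1.28 and 1.21. The SD of responses over all tested probes was 0.50 against 0.50, 0.53 and 0.53. Choosing on water alone can lower the shares, so no damping follows, and with 2 values each they were not tested. Median centring gave 65.4% (EGTA) and 65.8% (mastoparan), and processed signals 77.4% (lanthanum) and 76.0% (EGTA).

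At normal temperature, lanthanum against water asked what a calcium channel blocker alone changes. The Bowman-Birk inhibitor, a defence protein against proteases, rose 3.77-fold (1.91 ± 0.24), the thioredoxin fold protein by 1.67 ± 0.12 and CIPK22 by 1.57 ± 0.13. The nematode resistance homolog Hs1 rose by 1.48 ± 0.16 and a MutT/nudix protein by 1.36 ± 0.20. Senescence-associated protein rose by 1.69 ± 0.33 with unequal replicates (0.78 and 2.60, adjusted p = 0.0471). Its call ended with direct ratios (0.0501), median centring (0.124), processed signals (0.237), the value table (0.0796), no filter (0.0681) and the trend prior (0.0992). Beta-1,3-glucanase 2a fell by 1.77 (SE 0.21), and asparaginase, which releases nitrogen from asparagine, by 1.43 (SE 0.24). Under median centring the calls of MutT/nudix (0.0711) and asparaginase (0.0583) ended.

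The lists that moved under lanthanum at normal temperature did so by small changes, most of whose members did not pass singly. Abscisic acid genes moved up (1 rising of 25, 7 adjusted over the list alone, adjusted p = 7.54e-07). Jasmonate genes moved up (1 of 23, 3 adjusted over the list alone, adjusted p = 2.27e-05). WRKY, NAC and MYB factors did too (2 of 44, with 4 up and 1 down adjusted over the list alone, adjusted p = 0.000874), with a Myb factor at 1.35 ± 0.13. limma called 0 dehydrins (7 up adjusted over the list alone) and 0 histones (0 adjusted over the list alone) in lists that moved up (adjusted p = 1.49e-05 and 0.0023). It called 0 photosynthesis, cell wall and ribosomal protein genes (0 of each adjusted over the list alone) in lists that moved down (adjusted p = 7.46e-06, 0.00291 and 0.00633). At an unadjusted p under 0.05 there were 7 dehydrin and 11 histone probes higher, 8 photosynthesis probes lower, 2 cell wall probes higher and 12 lower, and 1 ribosomal probe each way. Direct ratios called 3 histone probes higher, 1 photosynthesis probe lower and 0 members of the other lists. The ribosomal list had replicate means of 0.02 and -0.09 and missed the threshold with processed signals (0.0615). No call held: adjusted p = 0.748 for the abscisic acid and WRKY lists, 0.419 for dehydrins, 0.93 for histones, 0.926 for ribosomal proteins and 0.902 for the rest with an estimated correlation.

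In all, lanthanum at normal temperature raised 272 probes and lowered 14 (2448 at an unadjusted p under 0.05, 76 and 2 at least 2-fold). Direct ratios called 414 and 41, all 40 arrays 2401, the fit without the replicate block 2885, median centring 72, processed signals 118 and the other slides alone 729. The count was 60 and 21 without normal water replicate 1 and 2, 149 and 158 without cold water replicate 1 and 2, and 59 without normal lanthanum replicate 2. It was 185 without cold lanthanum replicate 2 and 458 without cold mastoparan replicate 2.

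EGTA at normal temperature raised the ZIM motif protein 10.9-fold (3.45 ± 0.41) and the Bowman-Birk inhibitor 6.77-fold (2.76 ± 0.24). Senescence-associated protein (2.22 ± 0.33), a Myb family factor (2.05 ± 0.13) and an F-box protein (2.02 ± 0.16) rose too. hvnas2 rose by 2.53 ± 0.53 with replicates at 1.60 and 3.46 (adjusted p = 0.0164, but 0.154 with processed signals and 0.0547 with the value table). WIR1, a pathogen-induced wheat protein, was 5.70-fold lower (-2.51 ± 0.43). Beta-1,3-glucanase 2a (-2.02 ± 0.21), WIR1A (another probe than in the cold, -1.83 ± 0.27), a Streptomyces cyclase/dehydrase family protein (-1.46 ± 0.18), copper-zinc superoxide dismutase (-1.45 ± 0.17) and asparaginase (-1.21 ± 0.24) fell. Abscisic acid genes moved up (9 rising of 25, with 14 up and 1 down adjusted over the list alone, adjusted p = 1.97e-08), with 2 protein phosphatase 2C probes at 1.62 ± 0.16 and 0.96 ± 0.13. Dehydrins moved up (6 of 14, 8 adjusted over the list alone, adjusted p = 0.000861), with DHN1 at 0.60 ± 0.11. WRKY, NAC and MYB factors did too (10 of 44, with 14 up and 1 down adjusted over the list alone, adjusted p = 0.00577), with a WRKY factor at 1.55 ± 0.23. Jasmonate genes (6 of 23, 7 adjusted over the list alone, adjusted p = 0.00925), histones (8 of 176, 2 adjusted over the list alone, adjusted p = 2.71e-05) and gibberellin genes (2 of 13, 4 adjusted over the list alone, adjusted p = 0.0496) also moved up. Photosynthesis genes moved down, 1 rising and 12 falling of 46 (2 and 28 adjusted over the list alone, adjusted p = 1.13e-08). Cell wall genes did too (3 falling of 49, 3 adjusted over the list alone, adjusted p = 0.00543).

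None of these EGTA calls held: adjusted p = 0.62 for abscisic acid genes, 0.419 for dehydrins, 0.91 for histones and 0.902 for the others with an estimated correlation. Under median centring the jasmonate list, with replicate means of 0.50 and 0.03, missed the threshold (0.0512), as did the cell wall list (0.115). The gibberellin list did so with no background subtraction (0.0803), median centring (0.144), processed signals (0.13) and the value table (0.0528). In all, EGTA raised 1461 probes and lowered 1055 at normal temperature (228 and 25 at least 2-fold). Direct ratios called 1829 and 1430, all 40 arrays 7687, processed signals 1446 (989 and 457) and the other slides alone 4711, and median centring gave 1729 and 203. The count was 807 and 539 without normal water replicate 1 and 2, 889 and 1342 without normal EGTA replicate 1 and 2, and 1273 and 1303 without cold water replicate 1 and 2. It was 3854 and 3927 without cold mastoparan replicate 1 and 2.

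Mastoparan at normal temperature also raised the ZIM motif protein (9.20-fold, 3.20 ± 0.41), the Bowman-Birk inhibitor (2.69 ± 0.24), the thioredoxin fold protein (another probe than for lanthanum, 2.40 ± 0.10), the F-box protein (2.19 ± 0.16), the Myb factor (2.13 ± 0.13) and CIPK22 (2.07 ± 0.13). CBF4A fell by 1.23 (SE 0.14), the abscisic acid-induced ABA7 by 1.06 (SE 0.21), both peroxidase BP 1 entries by 0.89 and 0.86 and the Streptomyces cyclase/dehydrase protein by 0.84. Cyanate hydratase (another probe than in the cold) stood at -0.99 ± 0.24 (adjusted p = 0.0346), a call that ended under median centring (0.104), with processed signals (0.093), without the replicate block (0.0502) and with the trend prior (0.0525). Histones moved up, 33 rising of 176 (73 adjusted over the list alone, adjusted p = 9.68e-19), with H2B.1 at 0.65 ± 0.09. Abscisic acid genes did too, 5 rising and 1 falling (8 and 3 adjusted over the list alone, adjusted p = 0.00172), with a protein phosphatase 2C at 1.48 ± 0.13. Ethylene genes followed, 5 of 15 (5 adjusted over the list alone, adjusted p = 0.0478). The defence list (4 falling, 4 adjusted over the list alone, adjusted p = 7.01e-05) and the cell wall list (2 falling, 2 adjusted over the list alone, adjusted p = 0.000337) moved down, but the called probes are all of the thaumatin-like TLP5 and of xyloglucan endotransglycosylase. So did jasmonate genes (adjusted p = 0.0363), of which limma called 0 (0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05 and 0 with direct ratios). For each of these lists adjusted p = 0.902 with an estimated correlation. The ethylene call ended with direct ratios (0.0621), no background subtraction (0.0784), processed signals (0.204), the value table (0.0569) and the list without removals (0.187).

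In all, mastoparan at normal temperature raised 1171 probes and lowered 655 (183 and 15 at least 2-fold). Direct ratios called 1560 and 755, all 40 arrays 6275, the other slides alone 3247 and median centring 805 and 189. The count was 568 and 501 without normal water replicate 1 and 2, 678 and 1085 without normal mastoparan replicate 1 and 2, and 994 and 1079 without cold water replicate 1 and 2.

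**Figure D3:**
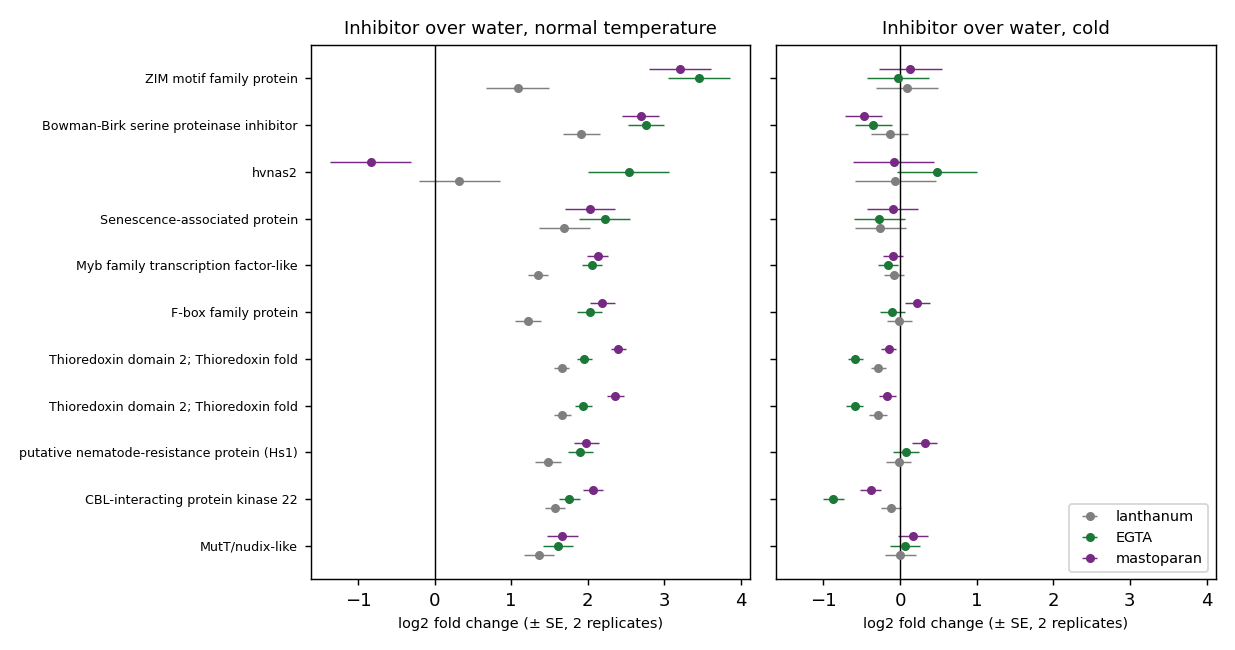
Log2 fold change of each inhibitor over water (horizontal axes, points ± SE, 2 replicates) at normal temperature (left) and in the cold (right) for the named genes that rose most under an inhibitor at normal temperature. Each line is 1 probe across inhibitors, with 2 probes of the thioredoxin fold protein.

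The inhibitors' effects overlapped at normal temperature. Of the 272 probes raised by lanthanum 227 were raised by EGTA as well and 215 by mastoparan, against 13.1 and 10.5 for independent lists, and EGTA and mastoparan shared 707 (56.3 for independent lists). The lower lists shared 10, 4 and 271 probes (0.486, 0.302 and 22.8 for independent lists). Part of this excess may come from the shared water extracts. Across probes, an inhibitor's effect in 1 replicate was therefore set against another's in the other replicate, which shares no extract. These correlated with r = 0.612 ± 0.10 (SD, n = 2) for lanthanum and EGTA, 0.396 ± 0.067 for lanthanum and mastoparan and 0.511 ± 0.033 for EGTA and mastoparan, with covariances of 0.0268, 0.015 and 0.0289. Within a replicate the covariances exceeded those simulated for shared extracts by 0.0216, 0.0167 and 0.0265. The simulated correlation was 0.316, 0.31 and 0.315 within a replicate and near 0 across.

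In the cold, few probes passed the threshold for lanthanum against water. DHN1 rose 2.09-fold (1.06 ± 0.11, adjusted p = 0.0282). Starch synthase IIIb-1 (0.82 ± 0.14), a stress responsive protein (0.76 ± 0.14), OJ991214_12.12 (0.72 ± 0.10), a hydrolase-like protein (0.69 ± 0.09) and photosystem II protein H (0.66 ± 0.12) rose. Peroxidase 5 (-0.62 ± 0.12), root abundant factor (-0.59 ± 0.09), cytoplasmic glutamine synthetase (-0.54 ± 0.09) and the vacuolar ATPase B subunit (-0.51 ± 0.09) fell. CER1;1, an enzyme of wax synthesis (-0.47 ± 0.06), and the aquaporin HvPIP1;4 (-0.47 ± 0.08) fell too. All 12 calls ended with the value table (adjusted p from 0.0605 to 0.0737) and 10 under median centring (0.0583 to 0.0755). Without the comparison's own slide starch synthase (0.39, adjusted p = 0.157), photosystem II protein H (0.44, 0.193) and glutamine synthetase (-0.29, 0.126) did not pass. The histone and DNA replication list moved up (3 of 176, 5 adjusted over the list alone, adjusted p = 7.01e-05, but 0.93 under median centring), but its 3 called probes are all of Cyclin-D6-1 and no histone was called. Dehydrins moved up (1 of 14, 4 adjusted over the list alone, adjusted p = 0.000326), and photosynthesis genes down although 1 rose (1 adjusted over the list alone, adjusted p = 0.00577). limma called 0 cell wall genes (3 lower adjusted over the list alone) and 0 jasmonate genes (0 adjusted over the list alone), though camera moved these lists down (adjusted p = 0.000955) and up (0.0107). At an unadjusted p under 0.05, 1 cell wall probe was higher and 14 lower, and 1 jasmonate probe higher. Direct ratios called 6 cell wall probes lower and 1 jasmonate probe higher. No list call held: adjusted p = 0.91 for histones, 0.419 for dehydrins and 0.902 for the others with an estimated correlation.

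In all, 96 probes were higher and 194 lower under lanthanum in the cold (5183 at an unadjusted p under 0.05, 9 and 0 at least 2-fold). Direct ratios called 599 and 876, all 40 arrays 5728, the fit without the replicate block 3301, no background subtraction 916, processed signals 511 and the other slides alone 659. Median centring called 5 (1 and 4), and the authors' values gave 3 higher and 0 lower. limma called 0 probes without normal EGTA replicate 1 (4770 at an unadjusted p under 0.05), normal mastoparan replicate 1 (5220), cold lanthanum replicate 1 (3599), normal water replicate 2 (3923) or cold lanthanum replicate 2 (2970). It called 2 without normal water replicate 1, 1 without cold water replicate 1, 2 without normal EGTA replicate 2 and 3 without normal mastoparan replicate 2. The count was 120 without cold EGTA replicate 1, 126 without cold water replicate 2, and 1685 and 1639 without cold mastoparan replicate 1 and 2.

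EGTA in the cold raised DHN1 4.18-fold over water (2.06 ± 0.11) and a stress-inducible membrane pore protein by 1.21 ± 0.17. DHN4 rose by 1.46 ± 0.42 with replicates at 0.64 and 2.27 (adjusted p = 0.036, but 0.0523 under median centring, 0.0574 with the value table and 0.0714 with the trend prior). Acyl carrier protein desaturase, which makes unsaturated fatty acids in plastids, rose by 1.14 ± 0.30 (0.90 from direct ratios, 1.79 from the other slides, adjusted p = 0.163 without the replicate block). PR17d rose by 0.91 ± 0.20 and the calcium-binding EFA27 by 0.90 ± 0.14. Peroxidase 5 was 3.14-fold lower (-1.65 ± 0.12). Farnesyl diphosphate synthetase (-1.42 ± 0.26), a cysteine proteinase (-1.35 ± 0.18), the expansin EXPB4 (-1.32 ± 0.17), laccase-7 (-1.19 ± 0.11) and fructose-bisphosphate aldolase (-1.15 ± 0.12) fell. Histones moved up (25 of 176, 20 adjusted over the list alone, adjusted p = 3.58e-13), with Cyclin-D6-1 at 0.60 ± 0.07. Ribosomal proteins did too (11 of 72, 11 adjusted over the list alone, adjusted p = 7.18e-07, but 0.181 under median centring), as did dehydrins (5 rising and 1 falling, 7 and 1 adjusted over the list alone, adjusted p = 0.000955). Cell wall genes moved down, 2 rising and 17 falling (3 and 21 adjusted over the list alone, adjusted p = 0.000326), with a polygalacturonase at -1.02 ± 0.11. Photosynthesis genes moved down, 3 and 12 (4 and 25 adjusted over the list alone, adjusted p = 0.00291), with the P700 apoprotein at -0.85 ± 0.12. No call held: adjusted p = 0.419 for dehydrins and 0.902 for the others with an estimated correlation.

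In all, EGTA in the cold raised 1852 probes and lowered 3679 (36 and 86 at least 2-fold). Direct ratios called 2755 and 4747 and all 40 arrays 11469. Median centring, which moved the median of all probes to -0.12, gave 385 and 7395, and processed signals 2914 and 2602. The count was 3050 and 3318 without normal water replicate 1 and 2, 297 and 2445 without cold water replicate 1 and 2, and 2961 and 1889 without cold EGTA replicate 1 and 2.

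Mastoparan in the cold lowered CER1;1 (another probe than for lanthanum) 3.15-fold (-1.65 ± 0.13), soluble acid invertase, which splits sucrose (-1.37 ± 0.14), a lipase-like protein (-1.34 ± 0.30), carbonic anhydrase (-1.29 ± 0.19), the cysteine proteinase (-1.27 ± 0.18) and ABA7 (-1.13 ± 0.21). It raised the thaumatin-like protein TLP4 (0.89 ± 0.14), chloroplast ribosomal protein S2 (0.86 ± 0.10), HSP90 (0.77 ± 0.13) and a glutathione transferase (0.74 ± 0.17). ATP synthase subunit beta rose by 0.79 ± 0.10 but missed the threshold without the replicate block (adjusted p = 0.396). Acyl carrier protein desaturase stood at 0.97 ± 0.30 (adjusted p = 0.0365), but at 0.54 with direct ratios (0.10) and 2.09 from the other slides. It also missed the threshold without the replicate block (0.194), with no filter (0.0511) and with the trend prior (0.0603). Histones moved up, 105 of 176 (121 up and 1 down adjusted over the list alone, adjusted p = 1.01e-22). Ribosomal proteins did too, 52 of 72 (58 adjusted over the list alone, adjusted p = 4.12e-19). Their medians of 0.28 and 0.31 fell to 0.05 and 0.10 under median centring and to 0.15 and 0.21 without cold mastoparan replicate 1. Phenylpropanoid synthesis moved down (16 of 37, 2 up and 18 down adjusted over the list alone, adjusted p = 0.000149), with caffeic acid O-methyltransferase, an enzyme of lignin synthesis, at -0.83 ± 0.10. Cell wall genes (4 and 17, 6 and 22 adjusted over the list alone, adjusted p = 0.000285) and photosynthesis genes (2 and 21, 3 and 25 adjusted over the list alone, adjusted p = 0.00345) moved down. Sugar metabolism did too (7 of 23 falling, 9 adjusted over the list alone, adjusted p = 0.00349), with galactinol synthase at -0.76 ± 0.15.

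Further lists moved down under mastoparan in the cold. Of cold-regulated protein probes 8 fell of 19 (1 up and 9 down adjusted over the list alone, adjusted p = 0.0052), with BLT4 at -0.66 ± 0.11 and WCOR413 at -0.48 ± 0.12. Of abscisic acid probes 9 fell of 25 (10 adjusted over the list alone, adjusted p = 0.0382, but 0.0738 under median centring and 0.099 with processed signals). Of ethylene probes 4 fell of 15 (4 adjusted over the list alone, adjusted p = 0.0104, but 0.0608 with direct ratios and 0.146 with processed signals), with ACC oxidase, which makes ethylene, at -0.56 ± 0.09. G protein and phospholipid signalling had 2 up and 8 down of 32 (2 and 8 adjusted over the list alone, adjusted p = 0.0496). That call ended with no background subtraction (0.0537), processed signals (0.133), the value table (0.0716) and the list without removals (0.805). For each of the 10 lists adjusted p = 0.902 with an estimated correlation. In all, 3434 probes were higher and 4320 lower in the cold under mastoparan (11 and 126 at least 2-fold). Direct ratios called 3965 and 5213, all 40 arrays 13108 and median centring 266 and 7345. The count was 5011 without normal water replicate 1, 829 and 4358 without cold water replicate 1 and 2, and 3543 without cold mastoparan replicate 1.

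**Figure D4:**
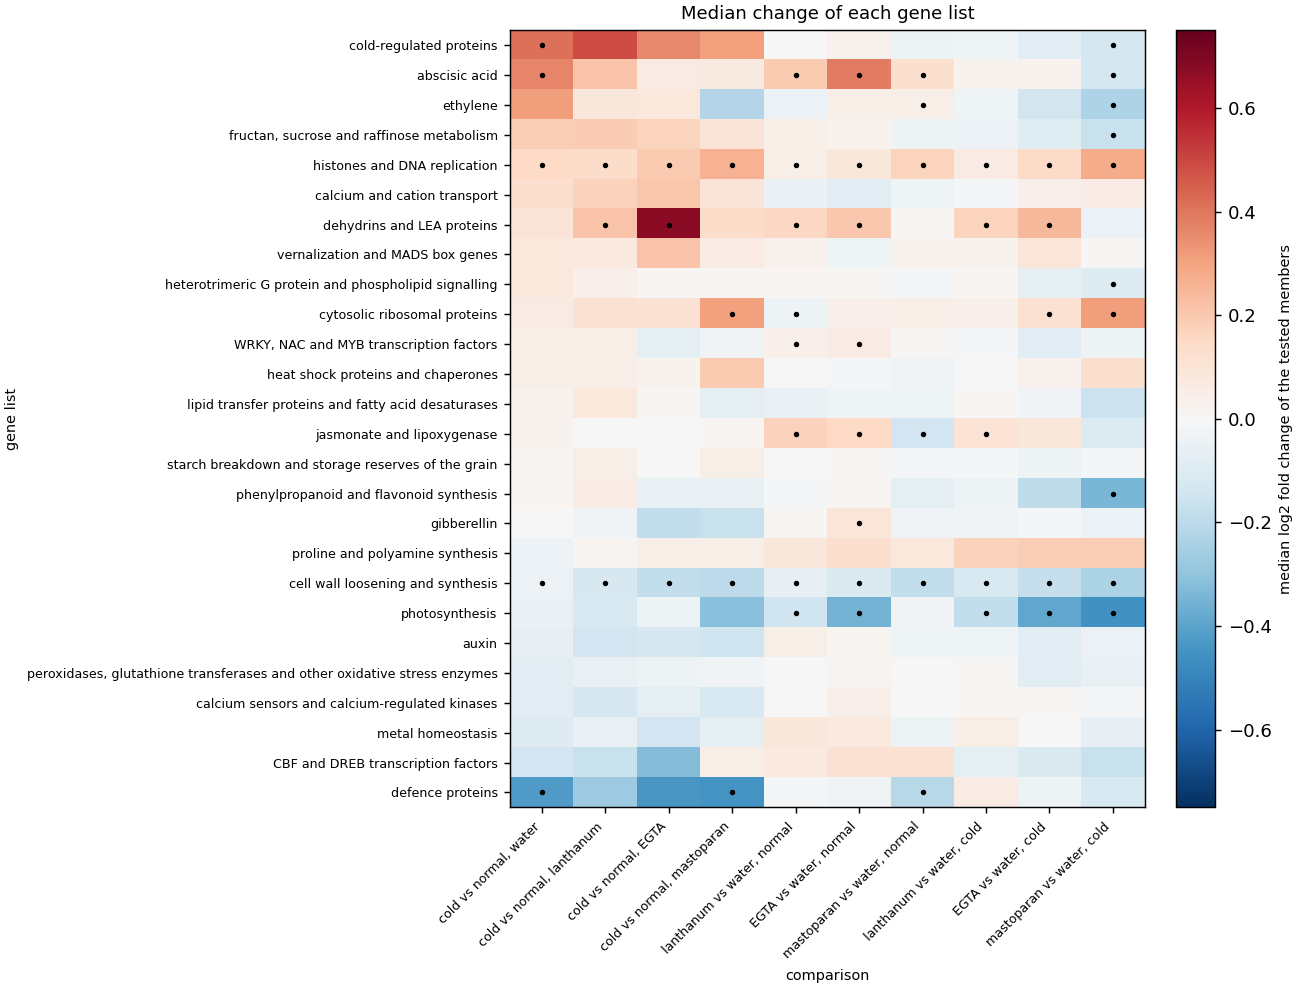
Median log2 fold change (colour) of the tested members of each of the 26 gene lists (vertical axis) in the 10 comparisons (horizontal axis), with dots for lists past an adjusted p of 0.05 by camera with the preset correlation. None passed with an estimated correlation, and under median centring the histone list's median after mastoparan in the cold moves from 0.28 to 0.05 and the histone list's call after lanthanum ends.

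In the cold, too, the inhibitors' calls overlapped. Lanthanum shared 91 of 96 raised probes with EGTA and 56 with mastoparan (5.85 and 10.9 for independent lists), and 190 and 183 of 194 lowered probes (23.5 and 27.6). EGTA and mastoparan shared 1156 raised and 2578 lowered probes (209 and 523 for independent lists). Part of the excess may come from the shared water extracts. Across replicates the effects correlated with r = 0.616 ± 0.006 (SD, n = 2) for lanthanum and EGTA, 0.521 ± 0.15 for lanthanum and mastoparan and 0.66 ± 0.056 for EGTA and mastoparan, with covariances of 0.0232, 0.0214 and 0.039. Within a replicate the covariances exceeded the simulated ones by 0.0229, 0.015 and 0.0328. The simulated correlation was 0.315, 0.312 and 0.311 within a replicate and near 0 across.

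The tested difference of cold responses (inhibitor minus water) equals the inhibitor's effect in the cold minus that at normal temperature. Either temperature alone can give it. Under lanthanum the response of beta-1,3-glucanase 2a was higher by 1.93 ± 0.29 (-0.80 against -2.72 after water). That of the Bowman-Birk inhibitor differed by -2.05 ± 0.34 (-2.10 against -0.05), the thioredoxin fold protein's by -1.95 ± 0.16, CIPK22's by -1.68 ± 0.19, a DNA-binding protein's by -1.58 ± 0.18, Hs1's by -1.50 ± 0.23 and the Myb factor's by -1.43 ± 0.19. With processed signals 5 of these 7 calls ended (glucanase, adjusted p = 0.0865, Bowman-Birk 0.111, CIPK22 0.0552, Hs1 0.0585 and Myb 0.104). Glucanase (0.0928) and Hs1 (0.0683) also missed the threshold under median centring, and Bowman-Birk with the value table (0.0515) and the trend prior (0.0518). WRKY, NAC and MYB factors (1 lower of 44, 6 adjusted over the list alone, adjusted p = 0.00291) and abscisic acid genes (1 lower of 25, 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.00468) had lower responses. limma called 0 auxin genes (2 lower adjusted over the list alone) in a list with lower responses (adjusted p = 0.009, but 0.098 with processed signals). It called 0 ribosomal proteins (0 adjusted over the list alone) in a list with higher ones (adjusted p = 0.00102, but 0.581 under median centring, replicate means -0.01 and 0.14). At an unadjusted p under 0.05, 1 auxin probe was higher and 5 were lower, and 2 ribosomal probes were higher. Direct ratios called 2 auxin probes lower and 0 ribosomal ones. No call held: adjusted p = 0.91 for ribosomal proteins and 0.902 for the others with an estimated correlation.

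In all, 7 probes had a higher and 153 a lower cold response under lanthanum (3410 at an unadjusted p under 0.05, 3 and 57 at least 2-fold). Direct ratios called 183 and 550, all 40 arrays 6130, no background subtraction 318, median centring 65, processed signals 14, the authors' values 88 and the fit without the water slide 273. The count was 37 and 9 without normal water replicate 1 and 2, 283 and 44 without normal lanthanum replicate 1 and 2, and 3 and 42 without cold water replicate 1 and 2. It was 24 and 3 without cold lanthanum replicate 1 and 2, 101 without normal EGTA replicate 2, and 315 and 375 without cold mastoparan replicate 1 and 2.

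Under EGTA the cold response of the ZIM motif protein was 11.1-fold lower than after water (-3.48 ± 0.57, with responses of -3.88 and -0.40). Those of the Bowman-Birk inhibitor (-3.11 ± 0.34), CIPK22 (-2.63 ± 0.19), the thioredoxin fold protein (-2.54 ± 0.16), Senescence-associated protein (-2.49 ± 0.47) and the Myb factor (-2.20 ± 0.19) were lower too. Responses of DHN1 (1.46 ± 0.16, with responses of 2.20 and 0.73), aleurone ribonuclease (1.38 ± 0.26) and a SINA-like protein, of a ubiquitin ligase family (1.33 ± 0.22), were higher. With processed signals the DHN1 difference was 0.69 (adjusted p = 0.416). Acyl carrier protein desaturase (2.04 ± 0.42), the chloroplast-encoded NAD(P)H-quinone oxidoreductase chain H (1.53 ± 0.28) and asparaginase (1.37 ± 0.34) had higher responses too. The desaturase's call ended without the water slide (0.11), as did that of chain H (log2 1.25), and asparaginase's under median centring (0.0544) and without the replicate block (0.0527). Abscisic acid genes had lower responses (9 of 25, 11 adjusted over the list alone, adjusted p = 0.000326), with 2 protein phosphatase 2C probes at -1.57 ± 0.19 and -1.23 ± 0.22. So had WRKY, NAC and MYB factors (10 of 44, 14 adjusted over the list alone, adjusted p = 0.000586) and sugar metabolism (4 of 23, 12 adjusted over the list alone, adjusted p = 0.00349, but 0.0667 under median centring), with trehalose-6-phosphate synthase at -1.97 ± 0.26. Histones had higher responses (5 of 176, 0 adjusted over the list alone, adjusted p = 0.0066), and so had ribosomal proteins (adjusted p = 0.00268), but both lists turned direction under median centring (0.348 and 0.594) and missed the threshold with direct ratios (0.204 and 0.176). Of the ribosomal proteins limma called 0 (0 adjusted over the list alone, 5 higher and 1 lower at an unadjusted p under 0.05, and 2 and 1 with direct ratios). No call held: adjusted p = 0.748 for the WRKY list, 0.95 for histones, 0.91 for ribosomal proteins and 0.902 for the others with an estimated correlation.

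In all, 988 probes had a higher and 2135 a lower cold response under EGTA than after water (86 and 309 at least 2-fold). Direct ratios called 1778 and 2617, all 40 arrays 12187, processed signals 1024 and 1305, and the fit without the replicate block 2046. Median centring gave 610 and 9401 and moved the median of all probes to -0.26. With loess it was -0.01, to which the changes given here are relative. The count was 814 and 701 without normal water replicate 1 and 2, 1303 and 1611 without normal EGTA replicate 1 and 2, and 604 and 1447 without cold water replicate 1 and 2. It was 1995 and 1648 without cold EGTA replicate 1 and 2, and 1990 without cold lanthanum replicate 2.

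Under mastoparan the cold responses of the Bowman-Birk inhibitor (8.97-fold lower, -3.16 ± 0.34), the ZIM motif protein (-3.06 ± 0.57), the thioredoxin fold protein (another probe, -2.54 ± 0.14) and CIPK22 (-2.45 ± 0.19) were lower than after water. So were those of trehalose-6-phosphate synthase, which makes a sugar signal (-2.25 ± 0.26), and the Myb factor (-2.22 ± 0.19). Those of the desaturase (1.99 ± 0.42, but adjusted p = 0.101 without the water slide), the SINA-like protein (1.32 ± 0.22), the arginine methyltransferase PRMT3 (1.21 ± 0.20), aleurone ribonuclease (1.20 ± 0.26), HSP90 (1.16 ± 0.18) and chloroplast ribosomal protein S2 (1.13 ± 0.14) were higher. Cytosolic ribosomal proteins had higher responses (21 of 72, 35 adjusted over the list alone, adjusted p = 2.89e-12). So had histones (15 and 2 of 176, 15 and 2 adjusted over the list alone, adjusted p = 0.00355), though the list turned direction under median centring (0.885) and missed the threshold with direct ratios (0.122). Heat shock proteins had higher ones as a list (3 and 3 of 62, 3 and 3 adjusted over the list alone, adjusted p = 0.0382, but 0.0598 with processed signals, replicate means 0.49 and 0.02). Abscisic acid genes (9 lower, 11 adjusted over the list alone, adjusted p = 0.000281) and ethylene genes (6 lower of 15, 8 adjusted over the list alone, adjusted p = 0.000997, but 0.0501 with processed signals) had lower ones. Sugar metabolism (6 lower, 6 adjusted over the list alone, adjusted p = 0.00352) and phenylpropanoid synthesis (2 and 8 of 37, 2 and 15 adjusted over the list alone, adjusted p = 0.0124) did too, with phenylalanine ammonia-lyase at -1.21 ± 0.24. Photosynthesis genes were also lower (2 and 5 of 46, 3 and 5 adjusted over the list alone, adjusted p = 0.0382), but not with no background subtraction (0.0555), processed signals (0.0886) or direct ratios (0.126). WRKY, NAC and MYB factors had 1 and 10 of 44 (1 and 11 adjusted over the list alone, adjusted p = 0.044, but 0.0559 with processed signals). No call held: adjusted p = 0.93 for histones, 0.91 for photosynthesis and 0.902 for the others with an estimated correlation.

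In all, 1766 probes had a higher and 2642 a lower cold response under mastoparan than after water (72 and 379 at least 2-fold). Direct ratios called 3434 and 3392, all 40 arrays 14269, no background subtraction 6892 and the fit without the replicate block 2823. Median centring gave 434 and 5576, with the median of all probes at -0.14. The count was 1100 and 1032 without normal water replicate 1 and 2, 2501 and 2495 without normal mastoparan replicate 1 and 2, and 685 and 2303 without cold water replicate 1 and 2. It was 2666 and 9210 without cold mastoparan replicate 1 and 2. The 3 differences share the water extracts of both temperatures.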

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

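Of the tests in this part, those on the probes raised by all 3 inhibitors at normal temperature were chosen after the result was seen; the differences of cold responses and the search for outlying arrays were planned.

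The cold response differed between an inhibitor and water for 160 probes under lanthanum, 3123 under EGTA and 4408 under mastoparan, by limma's test of the difference. The doubt below about the water plants applies to these differences too. Under lanthanum the largest differences were -2.05 for the Bowman-Birk inhibitor, -1.95 for the thioredoxin fold protein, -1.68 for CIPK22, -1.58 for the DNA-binding protein, -1.50 for Hs1 and -1.43 for the Myb factor, and 1.93 for beta-1,3-glucanase 2a. Under EGTA the ZIM motif protein had -3.48, Bowman-Birk -3.11, CIPK22 -2.63, the thioredoxin fold protein -2.54, Senescence-associated protein -2.49 and Myb -2.20. Under mastoparan Bowman-Birk had -3.16, ZIM -3.06, the thioredoxin fold protein (another probe) -2.54, CIPK22 -2.45, trehalose-6-phosphate synthase -2.25 and Myb -2.22.

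Higher responses under EGTA were those of acyl carrier protein desaturase (2.04), NAD(P)H-quinone oxidoreductase chain H (1.53), DHN1 (1.46), aleurone ribonuclease (1.38), asparaginase (1.37) and the SINA-like protein (1.33), and under mastoparan those of the desaturase (1.99), the SINA-like protein (1.32), PRMT3 (1.21), aleurone ribonuclease (1.20), HSP90 (1.16) and chloroplast ribosomal protein S2 (1.13). Without the water slide the calls of the desaturase and chain H ended. Asparaginase's ended under median centring (adjusted p = 0.0544) and without the replicate block (0.0527), and DHN1's with processed signals (0.416). The first 3 also ended without some single extracts.

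Single arrays stood apart within their comparison by Dixon's criterion for 4 arrays, in 8 of 60 array measures and 4 of 128 named genes; chance alone gives about 1 in 20. For lanthanum against water at normal temperature, the median green signal of replicate 1 array 1 was 114.7 (others 87.14 to 91.63) and the median red signal of replicate 2 array 2 was 86.97 (100.7 to 103.3). The share of spots well above background in green was 61.52% on replicate 1 array 1 of EGTA against water at normal temperature (67.38% to 68.03%) and 64.19% on replicate 2 array 2 of cold after EGTA (55.06% to 55.73%). Outlier spots numbered 87 on replicate 1 array 1 of cold after EGTA (23 to 28), 55 on replicate 2 array 1 of mastoparan against water in the cold (12 to 15) and 271 on replicate 1 array 1 of cold after water (23 to 38). The SD of log2 ratios was 0.2852 on replicate 1 array 2 of EGTA against water in the cold (0.2519 to 0.2559).

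Among genes, the desaturase read 2.10 on replicate 2 array 1 of EGTA against water in the cold (0.39 to 0.67 on the others), and the cysteine proteinase -0.13 on replicate 2 array 1 of mastoparan against water in the cold (-1.82 to -1.54). ZIM read -3.94 on replicate 1 array 2 of cold after EGTA (-4.10 to -4.08), and HV58 4.92 on replicate 2 array 2 of cold after mastoparan (5.19 to 5.23).

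Outside the tested probes, 79 of 13220 dim probes passed for cold after water when all were tested. Of 57 positive control probes 6 were well above background on at least 75% of spots and channels, against 1.68% of negative control spots.

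At normal temperature 198 probes rose under all 3 inhibitors (medians 0.69, 1.00 and 1.04 for lanthanum, EGTA and mastoparan), and 4 fell under all 3; in the cold the medians of the 198 against water were -0.11, -0.18 and -0.13. The tables argue against chance in the shared water extracts as the whole cause, because covariances across replicates, which share no extract, were 0.0268 for lanthanum and EGTA, 0.015 for lanthanum and mastoparan and 0.0289 for EGTA and mastoparan, against 0.0269, 0.0219 and 0.0318 within a replicate. They argue against the 3 slides or their scan, because without these slides the 262 probes called on the slides alone kept at least 0.926 of their median rise. Water plants at normal temperature that stood apart cannot be told apart from an effect of the inhibitors: the rise under lanthanum was 0.8292 of that under EGTA in 1 replicate and 0.506 in the other, and a bound of 0.75 in both was needed to exclude equal rises. A response to the pretreatment solutions common to the 3 inhibitors is the biological explanation that the design gives, and it may hold only if the water plants did not stand apart.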

How the results depend on the processing

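Of these alternatives, lists without removals, camera on direct ratios and each comparison without its own slide were chosen after seeing the data. Where a value moved, the cause was not tested, unless the alternative's own construction gives it: the 2-fold minimum and the extracts left out call fewer probes or rest on fewer samples, and all 40 arrays treat repeated readings of an extract as separate.

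Counts of probes past the threshold follow, in the order lanthanum, EGTA, mastoparan where 3 are listed. No background subtraction gave 916 for lanthanum in the cold and 318 and 6892 for the lanthanum and mastoparan differences. Median centring gave 72 for lanthanum and 994 for mastoparan at normal temperature, 5 for lanthanum in the cold, and 65 and 10011 for the lanthanum and EGTA differences. Processed signals gave 118 and 1446 for lanthanum and EGTA at normal temperature, 511 for lanthanum in the cold and 14 for its difference, and the authors' values 3 and 88 for the last pair. Direct ratios gave 455 and 1475 for lanthanum at normal temperature and in the cold, and 733 and 6826 for the lanthanum and mastoparan differences. All 40 arrays gave 2401, 7687 and 6275 at normal temperature, 5728, 11469 and 13108 in the cold and 6130, 12187 and 14269 for the differences. Without the replicate block, lanthanum had 2885 at normal temperature and 3301 in the cold, and the EGTA and mastoparan differences 2046 and 2823. Without the comparison's own slide the counts were 729, 4711 and 3247 at normal temperature, 659 for lanthanum in the cold and 273 for its difference. The 2-fold minimum left 1478, 1468, 1717 and 1715 for cold after water, lanthanum, EGTA and mastoparan, 78, 253 and 198 at normal temperature, 9, 122 and 137 in the cold and 60, 395 and 451 for the differences. An estimated correlation left 0 of 75 list calls.

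The share kept moved to 78.6% for EGTA with no background subtraction, to 65.4% for EGTA and 65.8% for mastoparan under median centring, and to 77.4% for lanthanum and 76.0% for EGTA with processed signals. With a log2 minimum of 2 it was 88.6%, 89.4% and 84.4%. Cross-replicate correlations in the cold moved for lanthanum and EGTA to 0.687 (median centring), 0.483 (processed signals), 0.51 (value table), 0.582 (no filter) and 0.632 (stricter filter), and for EGTA and mastoparan to 0.727 (median centring), 0.579 (processed signals) and 0.592 (value table). At normal temperature processed signals gave 0.493, 0.283 and 0.356 for lanthanum with EGTA, lanthanum with mastoparan and EGTA with mastoparan, and the authors' values 0.473 for the last pair.

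With each extract left out in turn, its partner assumed to vary like the other conditions, counts ran from 9436 to 17011 for cold after water, 12327 to 17430 after lanthanum, 13782 to 18440 after EGTA and 13028 to 18673 after mastoparan. They ran from 21 to 458, 539 to 3927 and 501 to 2533 at normal temperature, from 0 to 1685, 297 to 7668 and 829 to 11340 in the cold, and from 3 to 375, 604 to 4466 and 685 to 9210 for the differences.

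Direction turned under median centring for 3 list calls, ribosomal proteins (adjusted p = 0.594) and histones (0.348) in the EGTA difference and histones in the mastoparan difference (0.885), and for 9 list members: in cold after water DREB1 (0.092) and KO1 (0.21); under EGTA in the cold SPY (-0.053), KO1 (-0.081) and P5C dehydrogenase (-0.00068); under mastoparan in the cold SPY (-0.059) and TaAGL23 (-0.019); and in the EGTA difference a calmodulin-like protein (-0.083) and histone H1 (-0.14). Direct ratios turned a chloroplast HSP70 in the mastoparan difference (0.014). Of 943 named gene and comparison pairs, 936 kept direction and side of the threshold with no background subtraction, 775 under median centring, 800 with processed signals, 834 with the value table, 895 with no filter, 914 with direct ratios, 943 with all 40 arrays, 829 without the replicate block and 913 with the trend prior, and 889 of 939 did so without the slide and 851 of 851 with the stricter filter. Leaving out a water extract ended the most calls: 630 of 936 kept theirs without cold water replicate 1, 670 of 928 and 679 of 920 without normal water replicate 2 and 1, 734 of 943 without cold water replicate 2, and between 808 and 929 without each other extract. Of 338 list tests, 327 kept side and direction with no background subtraction, 294 under median centring, 320 with processed signals, 328 with the value table, 331 in lists without removals and 321 with direct ratios.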

Other observations

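Of the tests in this part, those of chloroplast tissue and of brightness for the chloroplast-encoded transcripts, and the random lists under median centring, were chosen after the result was seen.

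The 21 probes of chloroplast-encoded transcripts, a set named after the data were seen, moved down in the cold after water (median -0.56, 2 higher and 15 lower, camera adjusted p = 0.0045). At normal temperature they moved down under EGTA (-0.52, 14 lower, adjusted p = 4.91e-13), mastoparan (-0.25, 1 lower, adjusted p = 0.000196) and lanthanum (-0.09, 0 called, adjusted p = 0.00587). Their cold response was higher than after water under EGTA (median difference 0.59, 11 higher, adjusted p = 1.44e-10), mastoparan (0.43, 8 higher and 1 lower, adjusted p = 0.000607) and lanthanum (0.14, 0 called, replicates 0.46 and -0.01, adjusted p = 0.00293). None held: adjusted p = 0.758 for both EGTA results and 0.773 for the others with an estimated correlation. After EGTA the set did not pass for cold itself (median 0.14, 9 higher and 4 lower, adjusted p = 0.236), nor after mastoparan (-0.08, 4 and 9, adjusted p = 0.568) or lanthanum (-0.46, 4 and 12, adjusted p = 0.0642).

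In the cold these chloroplast-encoded probes stood above water after EGTA (median 0.22, 7 higher and 2 lower; adjusted p = 0.0413, and adjusted p = 0.826 with an estimated correlation) and mastoparan (median 0.16, 7 and 3; adjusted p = 0.0913). More chloroplast tissue would raise nuclear photosynthesis genes too, but the higher of the medians of their 25 probes was -0.43 (EGTA; -0.49 for mastoparan), which argues against it. Brightness-dependent normalization stays open: the 13 probes outside the named genes lay at percentiles 98.3 and 66.6 of brightness-matched random lists, and the full set, which held the genes that had led to it, at 100 and 99.1. Unequal priming of transcripts without a poly(A) tail cannot be told apart either, because mitochondrion-encoded transcripts, with a median of 0.44, had 2 probes. An effect of the pretreatments, which the design gives, was not tested apart from these.

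Histone and ribosomal protein probes stood higher in the cold after mastoparan than after water (medians 0.28 and 0.31). Brightness-dependent normalization did not give it: both medians lay at percentile 100 of 10000 matched random lists. No single extract gave the rise: the lowest ratio of a median without an extract to the full one was 0.558 (histones, without cold mastoparan replicate 1). Median centring in place of loess did move it (lower ratio 0.194), but no background subtraction, processed signals and the value table little (0.98 to 1.12). Under median centring the median of all probes moved to -0.09. Both lists still lay at percentile 100 of matched lists there (upper tails from -0.16 and -0.11). So the size of the rise may be a matter of normalization, while its rank above other probes was not. A change in dividing or growing cells of the stem base under mastoparan stays untested.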
